A study of Mus musculus with 32 samples.

How the data were processed

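FoxP3-YFP-positive CD4 T cells were sorted from cultured splenocytes, and single cells were captured with the 10x Genomics Chromium 3′ chemistry, per the labels' protocols. The submitters' processing notes name Cell Ranger 6.0.1 and the build mm10 without saying what each was used for. The annotation release, the cell calling settings and any filter on cells are not given in the sources used here. How the authors treated doublets is not given either, and none were called or removed here, since that needs UMI counts, so a barcode can stand for more than 1 cell. The deposited lists are, per their names, those of the filtered matrix, that is of the barcodes kept as cells. The files hold text and no measured unit: 1 barcode per line, made of 16 bases and a suffix that was the same throughout, or a feature identifier, a symbol and a feature type per line, with 1 feature type throughout. UMI counts, and all ATAC-seq and CUT&RUN data, were not analysed here. The tests planned for those data (ratios of CPM, and count or signal tests per region with and without pairing by replicate number) were therefore not run.

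Samples were grouped by their titles, which give the assay, the factor, the treatment and the replicate. The label SA was read as sphinganine, since the treatment protocol names no other treatment besides DMSO. Barcodes were compared between lists as written. The interval of a share is the exact Clopper-Pearson interval at 95%. The size of a barcode pool that would give the observed sharing by chance was taken as the product of the list lengths over the shared number, with the exact Poisson interval of that number. Chance sharing was also estimated by parting each barcode after base 7 and shuffling the second parts within each list 1000 times with a fixed seed, which keeps how often each part was used in each list. The parting point was chosen after the barcodes were seen. The 960 first parts did not rise in number between 6 and 7 bases, and base 9 followed from base 8 in every barcode. No base of the first part shared more than 0.000545 bits of information with a base of the second, against up to 0.0301 bits within the first part. These values are for pairs of bases and cannot show a rule that spans several bases. The procedure was tested on simulated lists of the same or nearly the same lengths. These lists combined their parts freely, as the shuffle assumes, so the test does not cover a pool that holds only some combinations. With 800 shared barcodes added, 796.1 were recovered as excess. With 100 added, 92.5 were recovered, and with 0 added the excess was 5.7.

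Gene lists were fixed before the data were examined and matched to the features by exact symbol; all of their genes are summarised in the report and none was chosen by a value. Of the 32286 feature identifiers, 32158 were in the reference table of gene names, and 31436 had the same symbol there. Feature symbols were used as the files give them. Coordinates are from the RefSeq annotation of GRCm38.p6, matched by symbol and counted from 1. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. The alternatives tried were matching without the suffix, within 1 base or with 1 list reverse-complemented, wider or narrower definitions of neighbouring barcodes, other parting points, symbols matched without regard to letter case, and repeated symbols counted once.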

Results

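The study examined regulatory T cells made in culture from mouse spleen. Splenocytes came from mice that carry the OT-II T cell receptor, which recognises an ovalbumin peptide, and a fluorescent YFP reporter of Foxp3, the transcription factor that defines regulatory T cells. The cells were grown for 2 to 3 days with the ovalbumin peptide at 1 μg/ml, interleukin-2 at 10 ng/ml and transforming growth factor β at 5 ng/ml. They received either sphinganine, a sphingoid base formed early in sphingolipid synthesis, at 5 μM (the samples labelled SA), or the DMSO vehicle. YFP-positive CD4 T cells were then sorted. The stated question was how sphinganine raises Foxp3 expression, and whether it changes which chromatin is open and where the transcription factors NFAT2, c-Jun and c-Fos bind.

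The series held 32 samples. There were 2 single-cell RNA-seq libraries, 1 per treatment, 6 ATAC-seq libraries, 3 per treatment, and 24 CUT&RUN libraries. CUT&RUN maps a protein's binding sites by cutting the DNA around a bound antibody, and here there were 3 libraries per treatment for each of NFAT2, c-Fos, c-Jun and the input. Only the list of cell barcodes and the list of counted genes of each single-cell library were used. Neither holds a measured level. Gene expression in single cells, accessibility and factor binding were not analysed here, so no gene, peak or cell type is described as higher or lower with sphinganine. Total UMI counts and depth per cell are likewise unknown here.

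Both single-cell libraries were counted against the same list of 32286 features, identical in content and order. Of these, 32285 carried Ensembl mouse gene identifiers and 1 was an added entry named YFPCre. By its name this entry stands for a YFP and Cre sequence, which was not examined. If it holds the reporter, reporter reads could be counted apart from Foxp3 (ENSMUSG00000039521). The gene lists below were fixed before the data were examined, and 196 of their 197 genes were among the features. Being listed or present here means that a gene could be counted, not that it was detected in either library. All 24 regulatory T cell genes were present, among them Foxp3, Il2ra, which encodes the interleukin-2 receptor α chain, and the inhibitory receptor gene Ctla4. All 12 genes of the AP-1 family list were present, including Fos (ENSMUSG00000021250), Jun (ENSMUSG00000052684), Junb and Batf. The 15 genes of NFAT and early T cell activation were all listed, including Nfatc1 (ENSMUSG00000033016), which encodes NFAT2.

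Genes of the metabolism that the study concerns could be counted as well. All 23 sphingolipid genes were listed, including Sptlc1 and Sptlc2, subunits of the serine palmitoyltransferase that starts sphingolipid synthesis, Kdsr, whose product makes sphinganine, and Cers2, one of the ceramide synthases that use it. All 14 genes of serine and one-carbon metabolism were listed, with Phgdh, Psat1 and Psph of serine synthesis among them. The 14 cholesterol and lipid genes, 16 effector T cell genes, 9 genes of naive and memory T cells and 15 proliferation genes were present too. So were the markers of cells that a sort can carry over: 6 of B cells, 8 of myeloid and dendritic cells, 6 of CD8 T and NK cells and 5 of erythroid cells. The 7 T cell identity genes, 8 mitochondrial genes and 8 stress genes were likewise all present. One of the stress genes, Ddit3, stood on 2 rows with different identifiers (ENSMUSG00000025408 and ENSMUSG00000116429). Of the 10 interferon-response genes, 9 were listed and Mx1 was not. The RefSeq annotation of GRCm38.p6 gives Mx1 as a transcribed pseudogene at chromosome 16, 97447035 to 97462906.

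In that annotation, which is of the same assembly as the mm10 build named for the series, Foxp3 lies on chromosome X from 7579676 to 7595243. Fos lies on chromosome 12 from 85473890 to 85477274. Jun lies on chromosome 4 from 95049036 to 95052222, and Nfatc1 on chromosome 18 from 80606205 to 80713071. All 4 were matched by symbol and are annotated as protein coding. T cell receptor segments were listed as separate features, which does not show that reads of any segment were captured in these libraries. The features included 128 α-chain V, 60 α-chain J, 35 β-chain V and 14 β-chain J segments, the single α constant gene Trac and 2 β constant genes.

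The DMSO library had 16734 cell barcodes and the sphinganine library 11573. With 1 library per treatment, no replicate check exists and no test was made, and the number of barcodes called in a library depends on how many cells were loaded and how cells were called. No barcode was repeated within either list. In both lists no pair of barcodes differed at a single base, out of 140005011 pairs in the DMSO library and 66961378 pairs in the sphinganine library. Between the lists 0 pairs differed at 1 base as well, so this absence is no trait of either library. Pairs that differed at 2 bases numbered 1322 within the DMSO list, 576 within the sphinganine list and 1780 among the 193662582 pairs between the lists.

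Of the 27420 barcodes found in either list, 887 were in both. These were 5.30% of the DMSO list (exact Clopper-Pearson 95% interval 4.97 to 5.65) and 7.66% of the sphinganine list (7.19 to 8.16). The intervals cover counting error only. Each 16-base barcode fell into a first part of 7 bases, of which 960 different ones were seen, and a second part of 9 bases, of which 3839 were seen. When the second parts were shuffled among the barcodes of each list 1000 times, the lists shared 53.8 ± 7.24 barcodes (mean ± SD over shuffles), and between 31 and 82. The observed number was 16.5 times this mean. The shuffle lets any first part meet any second part, so its mean is a chance level for freely combined parts only. Other parting points gave lower means, listed below.

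**Figure D1:**
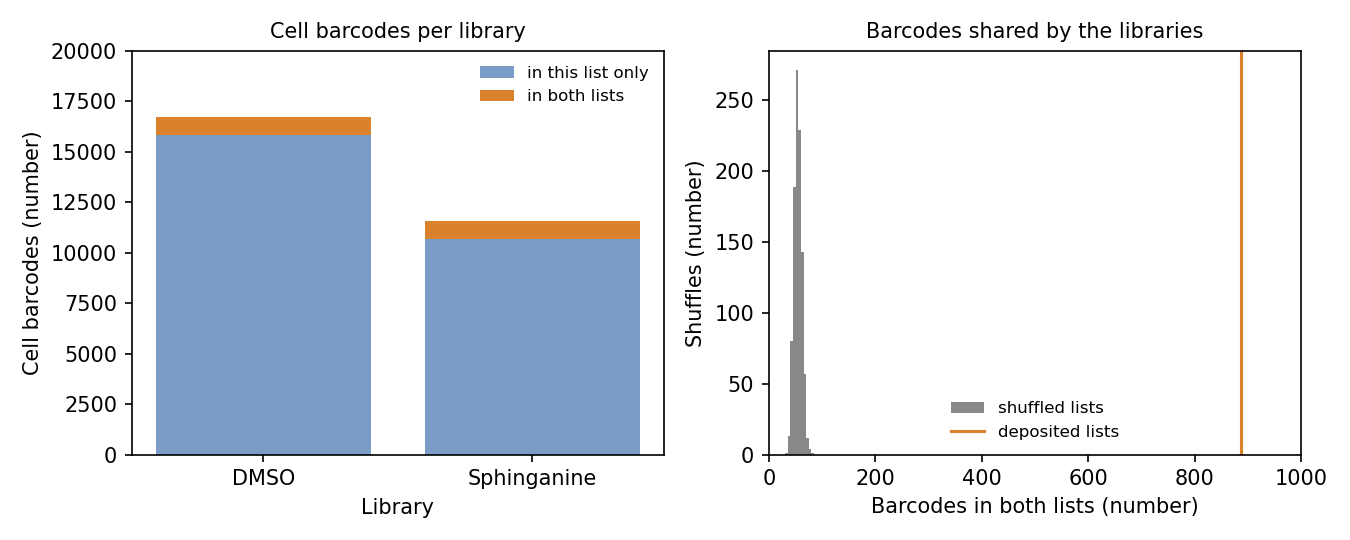
Left, number of cell barcodes in each library, split into those in 1 list (blue) and those in both (orange); right, number of barcodes shared by the lists, as a histogram over 1000 shuffles of the barcode parts (grey, y axis in shuffles) and as deposited (orange line). The deposited lists share 887 barcodes and the shuffled lists at most 82.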

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

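Leaving out the suffix, or allowing a match within 1 base, could not move the 887 shared barcodes, since the suffix was the same throughout and 0 pairs between the lists differed at 1 base, so neither says anything about stability. With 1 list reverse-complemented, 0 barcodes were shared, so the sharing was seen only with both lists read in the same direction. Reversed barcodes need not start with 1 of the 960 first parts seen, so 0 could arise whatever caused the sharing. This alternative therefore says nothing about stability or cause either. The absence of neighbouring barcodes held for a distance of exactly 1 over all 16 bases. Counting pairs that differ at 1 or 2 bases gave 1322 pairs in the DMSO list and 576 in the sphinganine list, and leaving out the first and last base gave 381 and 146; wider definitions count more pairs by construction. The chance number of 53.8 became 14.2, 14.0 and 16.2 when barcodes were parted after base 6, 8 or 9, alternatives added after the data were seen. The parting point used thus gives the highest chance level of those tried. All of them let the parts combine freely, so none sets an upper limit on chance sharing. Counting repeated symbols once left 32246 of 32286 features, and ignoring letter case left 196 list genes. The other settings chosen before the data were examined, for expression, ATAC-seq and CUT&RUN, were not run. No paired analysis was possible because the only files used belong to 1 library per treatment and hold no measured values. Without UMI counts, the depth of the libraries sets no limit that can be stated here.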

Other observations

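The lists share more barcodes than free chance combinations of their parts give, 887 against 53.8 after shuffling. The shuffle takes any first part to combine with any second, so a limited set of combinations would raise the chance number. Of the tests in this part, the one on the spread over first parts was set before its result was seen, and the others were chosen after the sharing was seen. A single library deposited under both labels is argued against, since 7.66% of the shorter list was in the longer one and a repeated library would give most of it. Chance meeting of freely combined parts, used at their observed rates, is argued against as the whole cause, since the highest shuffled number was 82. The sharing also did not sit on a few barcode starts. Shared barcodes per first part were compared with a number expected in proportion to all barcodes with that part. The variance to mean ratio, weighted by this expectation, was 1.02. It lay inside the range of 0.847 to 1.10 over 1000 random reassignments, and 567 first parts had at least 1 shared barcode.

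Open technical explanations remain, and they cannot be told apart here. Reads of one library may have been assigned to the other, for example by switching of sample indexes when libraries are sequenced together. This could account for all or part of the excess of about 833.2 barcodes over the shuffled mean. The other is a bead pool that holds few of the possible combinations of parts, and both may act together. The shuffle does not allow for such a pool, so with one the excess left for misassigned reads would be smaller than 833.2. As the whole cause, such a pool would need about 218334 barcodes (204426 to 233447), or 5.92% of the 3685440 combinations of the parts seen. UMI counts per barcode would decide the first, since misassigned barcodes should have few UMIs in one library, and the kit's own barcode list would decide the second. Neither was used here, and no biological explanation was tested. Until then, whether the 887 barcodes stand for separate cells in each library is open, for 5.30% of the DMSO and 7.66% of the sphinganine barcodes.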
